A study of Mus musculus with 12 samples.

How the data were processed

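Messenger RNA was sequenced from the prostate of male mice of the F1 and F3 generations after exposure of pregnant females to chlordecone, also called kepone, an organochlorine insecticide. Per the labels' protocols, the pregnant females (F0) were dosed with 100 µg/kg/day from embryonic day 6.5 to 15.5, the F1 offspring were bred on to F3, total RNA was extracted with a column kit, and stranded poly-A libraries were prepared. The labels list 12 samples in 4 groups of 3, and 11 of these libraries were analysed here. The library of F1 control 3 was not analysed here, so the F1 comparison set 2 control against 3 chlordecone libraries, although it was planned as 3 against 3. Columns headed C were read as control and columns headed K as chlordecone, from its other name kepone in the labels, with the sample number following the letter. No column of any other sample was left over (0 columns). The labels do not say whether samples were separate animals or pools, or whether they shared a litter or a dosed female. Every p-value therefore measures only the spread between these samples, not that between dosed females.

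For each generation the authors deposited 1 table of raw read counts per Ensembl gene, with their own log2 fold change, p-value and adjusted p-value for chlordecone against control. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, TopHat2 2.0.14, Bowtie2 2.1.0, HTSeq 0.6.1 and DESeq2 1.6.3 with the mm10 build. The annotation release and the strand setting of the counting are not given in the sources used here, so a gene and a partner on the other strand, or an overlapping gene, are reported as uncertain. The deposited counts were whole numbers with a different total in each library. The F1 table held 19091 genes, none of them mitochondrial, and the lowest total count of a gene over its libraries was 20. The F3 table held 26023 genes, 27 of them mitochondrial, with a lowest total of 1. The tables therefore went through different steps, and chlordecone was tested against control within each table, with the difference between generations tested in 1 fit of both. Levels set side by side across the tables are descriptions only.

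Gene coordinates are those of GENCODE M21 (GRCm38), matched by Ensembl identifier. Of the F1 identifiers, 19082 matched, and 2.11% of those had the same start and end in the deposited table, while 98.2% had the same span. Of the F3 identifiers, 25835 matched and 78.9% had the same start and end. The coordinates printed here are therefore those of the annotation.

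Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood F test, two-sided, was applied within each generation with no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Levels are in CPM, counts scaled to library size with the TMM factors, as mean ± SD over libraries, and fold changes are on the log2 scale, chlordecone over control. A gene with 0 counts in every library of a group was given a fold only as a lower bound, against a floor of 3 counts per library, and floors and counts cover counting error only. The difference between generations was tested as an interaction in 1 fit of all 11 libraries over the genes in both tables, with 1 mean per group. Genes past the threshold in both generations were compared with Fisher's exact test, two-sided, for each direction.

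Before the data were examined, 32 gene lists were fixed: prostate products, hormone pathways, the Hox family, cell types of the prostate, other tissues that a dissection can carry, and general pathways. Lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. For each list the adjusted p with an estimated correlation is given as well, and fry was run as an alternative. Members past the threshold were counted over all genes tested and adjusted over the list alone.

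Genes are named by a rule fixed at the same time. In each generation it took, among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a numbered gene model or clone, the 12 with the largest and the 12 with the lowest log2 fold change. Where fewer than 3 passed in a direction, the 5 with the smallest unadjusted p in that direction were named as well and are said to miss the threshold. Up to 6 interaction genes with the smallest p were named, and up to 4 members of a list, first those past the threshold over the list alone and then those with the highest mean CPM. Gm8399 and Trim5 in F3 fall outside this rule.

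Alternatives fixed at that time were DESeq2 size factors, no filter, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, 1 fit of all libraries, the replicate number as a block, and leaving out each library in turn. For the lists they also included an estimated correlation and fry, and for the overlap an unadjusted p. Added after the data were seen were newer quasi-likelihood moments in edgeR, limma voom with library quality weights, F1 without chlordecone 1 and 3 together, the mixed fry test and Fisher's exact test for genes in opposite directions. Neighbouring genes were counted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 against 10000 random draws of genes matched in 10 bins of expression.

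The tests were tried on simulated counts with the real means and library sizes and 200 changed genes, 100 at each size. In the F1 design, over 17804 genes, edgeR recovered 1% of the genes with a log2 change of 1 and 69% of those with a change of 3, with 6 false calls, and DESeq2 recovered 8% and 83%, with 37 false calls. In the F3 design, over 16766 genes, edgeR recovered 58% and 99% with 7 false calls, and DESeq2 81% and 100% with 44 false calls. Figures were drawn with matplotlib 3.10.9.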

Results

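The prostate transcriptome was measured by RNA sequencing in male mice whose mothers (F1), or more distant foremothers (F3), had received chlordecone during pregnancy, and in control males of the same generation. Chlordecone is an organochlorine insecticide with oestrogen-like activity. Of 12 samples in the labels, 11 libraries were analysed: 2 F1 controls, 3 F1 chlordecone, 3 F3 controls and 3 F3 chlordecone. Total counts were 17228539 and 18740109 in F1 control 1 and 2, and 25384743, 17858215 and 28061760 in F1 chlordecone 1, 2 and 3. They were 99547517, 71672418 and 114762135 in F3 control 1, 2 and 3, and 112491139, 86552953 and 102772803 in F3 chlordecone 1, 2 and 3. Svs4, a secretory protein of the seminal vesicle, was the most abundant transcript of every F1 library and took between 3.13% and 29.8% of the counts, the highest share being that of chlordecone 2. In every F3 library the most abundant transcript was 9530053A07Rik, at 11.6% to 16.6%. The chi-square per gene, which grows with depth, was 16.9 between the 2 F1 controls, the lowest of all pairs within a generation. The other F1 pairs had 285 to 645. Control 1 and 2 against chlordecone 2, a library of like depth, had 329 and 333, so depth alone does not account for the low value. Each control was counted as a sample because the labels list it as one, and the value does not show whether they are separate animals. If they are not, the F1 p-values are too small. The r of log2 CPM between these 2 controls was 0.904, below the 0.952 of F1 chlordecone 1 and 3 and below every F3 pair.

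The F1 comparison asks which prostate transcripts differed between males exposed in the womb and unexposed males. Cyp21a1, which encodes the steroid 21-hydroxylase of corticoid synthesis, rose from 0 counts in both controls to 25.5 ± 8.35 CPM (SD, n = 3), at least 171-fold higher against a floor of 0.149 CPM. Kcna2, a voltage-gated potassium channel subunit, rose from 2.70 ± 0.178 CPM (SD, n = 2) to 36.4 ± 10.3 CPM (n = 3), 13.4-fold. Fam199x fell from 245 ± 3.81 to 6.12 ± 2.14 CPM. C1rl, a complement C1r-like protease, fell from 80.7 ± 7.24 to 4.42 ± 1.90 CPM, and Scn3a, a voltage-gated sodium channel subunit, from 58.1 ± 7.24 to 8.71 ± 1.62 CPM. All 3 chlordecone libraries lay on the same side of both controls for these 5 genes.

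**Figure D1:**
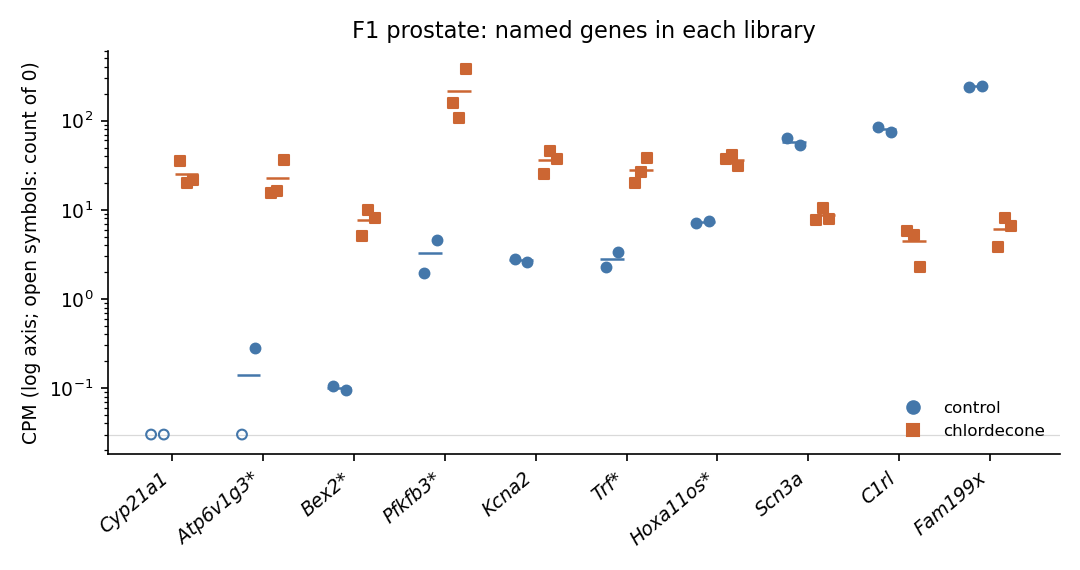
CPM (log axis) of the named genes in each F1 library, control (2 libraries, circles) and chlordecone (3 libraries, squares), with horizontal lines at the group means and open symbols for a count of 0. Genes with an asterisk miss the threshold; Fam199x stands at 242 and 247 CPM in the controls and at 8.02 CPM or less in every chlordecone library.

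These were all the genes past the threshold among 17804 tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2 higher and 3 lower. The log2 fold changes were 3.75 (SE 0.37, adjusted p = 0.0284) for Kcna2, -5.32 (SE 0.37, adjusted p = 0.0102) for Fam199x, -4.19 (SE 0.41, adjusted p = 0.0284) for C1rl and -2.74 (SE 0.27, adjusted p = 0.0284) for Scn3a, and the adjusted p of Cyp21a1 was 0.0163. Cyp21a1 lies on chromosome 17 from 34801348 to 34804561 beside a near-identical pseudogene copy and over Tnxa on the other strand, so its reads are uncertain. Kcna2 lies on chromosome 3 (107101146 to 107115005), Fam199x on chromosome X (137049594 to 137082503), C1rl on chromosome 6 (124493113 to 124510643) and Scn3a on chromosome 2 (65457118 to 65567627), all in GRCm38. C1rl and Scn3a overlap numbered gene models on the other strand. DESeq2 called 700 genes, 537 higher and 163 lower, with all 5 among them, and 2053 genes had an unadjusted p under 0.05, where chance gives 890. Groups did not overlap in 31.3% of the genes, against 20% if the 5 libraries fell in random order. The 2 controls had the lowest chi-square per gene, and controls that lie close together raise this share. By itself the 31.3% is therefore no sign of an exposure difference. The edgeR count was 0 without control 1 (1066 genes at an unadjusted p under 0.05), 0 without control 2 (1059 genes) and 0 without chlordecone 3 (1240 genes), 7 without chlordecone 1 and 2604 without chlordecone 2. Of the 5 genes, adjusted p lay between 0.204 and 0.711 without control 1, between 0.210 and 0.874 without control 2 and between 0.0807 and 0.188 without chlordecone 3, and that of Scn3a was 0.0558 without chlordecone 1.

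Another 5 genes had the smallest p among higher genes and missed the threshold at an adjusted p of 0.0629 each with edgeR. Pfkfb3, which makes the activator of phosphofructokinase in glycolysis, was at 3.29 ± 1.91 CPM in controls and 216 ± 145 CPM in chlordecone libraries. Trf, the iron carrier transferrin, was at 2.79 ± 0.760 and 28.1 ± 9.44 CPM. Pfkfb3 and Trf overlap numbered gene models, so their reads are uncertain. Bex2 was at 0.0993 ± 0.00782 and 7.71 ± 2.41 CPM, and Atp6v1g3, a proton pump subunit, at 0.141 ± 0.199 and 22.5 ± 11.8 CPM. Hoxa11os, which runs antisense to Hoxa11 and whose reads are therefore uncertain, was at 7.28 ± 0.370 and 36.5 ± 5.24 CPM.

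Of the 31 lists tested in F1, 12 passed camera, 11 higher and 1 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.423, 1 list at an unadjusted p under 0.05) or with directional fry (lowest adjusted p = 0.153, 4 lists at an unadjusted p under 0.05). The mixed fry test, which ignores direction, passed 5. None of their members passed over all genes with edgeR, so the counts below are adjusted over the list alone. Prostate products fell: the median log2 fold change of 9 members was -0.77 (camera adjusted p = 0.000739, adjusted p = 0.423 with an estimated correlation), 8 were lower and 0 passed adjusted over the list alone. Tgm4, a transglutaminase secreted into the copulatory plug, had 8259 ± 127 CPM in controls and 4137 ± 1278 CPM in chlordecone libraries. Spinkl, a protease inhibitor-like secretory protein, had 6334 ± 642 and 4697 ± 6329 CPM. Its SD in chlordecone libraries exceeded its mean, so it does not speak for a fall. Hoxb13, a homeobox regulator of the prostate epithelium, had 175 ± 9.63 and 103 ± 10.8 CPM. Pbsn, probasin, was at 78944 ± 10556 and 67245 ± 26034 CPM. The smooth muscle list rose, with all 15 members higher and a median of 1.06 (camera adjusted p = 9.72e-09, adjusted p = 0.423 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, had 115 ± 0.485 and 592 ± 324 CPM, and Smtn, smoothelin, had 16.2 ± 0.649 and 65.6 ± 18.4 CPM, 2 of the 6 that passed adjusted over the list alone. Without chlordecone 1 the median of the smooth muscle list was 0.64. Basal epithelium rose, with a median of 0.78 over 11 members (camera adjusted p = 0.0157, adjusted p = 0.423 with an estimated correlation), and Krt5 and Krt14, the basal keratins, passed adjusted over the list alone. The call of the basal list ended without control 1 (adjusted p = 0.223) and without chlordecone 2 (adjusted p = 0.133).

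The Hox family rose in F1, 22 of 34 measured members being higher and 12 lower, with a median of 0.87 (camera adjusted p = 0.000684, adjusted p = 0.423 with an estimated correlation). Of these, 8 passed adjusted over the list alone, all of the B and D clusters: Hoxd9 had 4.48 ± 1.08 CPM in controls and 17.5 ± 2.63 CPM in chlordecone libraries, Hoxb6 had 5.86 ± 1.25 and 39.5 ± 24.2 CPM, and Hoxd8 had 5.49 ± 0.581 and 36.4 ± 21.6 CPM. Without chlordecone 2 the median of the Hox list was 0.48. Xenobiotic metabolism rose, with 16 of 19 members higher and a median of 1.53 (camera adjusted p = 1.14e-05, adjusted p = 0.423 with an estimated correlation), or 2.30 without control 2. The glutathione transferases Gstm1 (12.5 ± 1.55 and 79.4 ± 63.0 CPM) and Gstp1 (17.6 ± 2.95 and 72.7 ± 37.6 CPM) and the cytochrome Cyp1a1 (0.204 ± 0.156 and 3.03 ± 1.39 CPM) were among 6 that passed adjusted over the list alone. Cell adhesion genes rose with a median of 0.74 over 25 members (camera adjusted p = 0.0201, adjusted p = 0.423 with an estimated correlation), 4 passing adjusted over the list alone, among them the tight junction gene Cldn1 (13.2 ± 0.310 and 45.8 ± 17.0 CPM). The median of that list was 0.28 without chlordecone 2, and its call ended without control 2 (adjusted p = 0.0541).

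Lists of tissues beside the prostate also rose in F1, and unevenly between the libraries. Vas deferens and epididymis markers had a median of 3.43 over 6 members (camera adjusted p = 0.00405, adjusted p = 0.423 with an estimated correlation). Akr1b7, an aldo-keto reductase of the vas deferens, was at 15.3 and 14.8 CPM in the controls and at 29064, 33.2 and 8741 CPM in chlordecone 1, 2 and 3, and Crisp1, an epididymal secretory protein, at 8.70, 10.1, 15224, 68.5 and 5188 CPM in the same order. Both passed adjusted over the list alone. The median of that list was 6.33 without control 1 and 6.76 without chlordecone 2. Urothelium rose with a median of 3.40 over 8 members, 5 passing adjusted over the list alone (camera adjusted p = 0.000244, adjusted p = 0.423 with an estimated correlation), and its median log2 ratio to the controls was 3.96, 0.99 and 3.22 in chlordecone 1, 2 and 3. The xenobiotic list stood at 1.82, 0.55 and 2.01 in these libraries. Adipose tissue (median 1.37, camera adjusted p = 0.000152, adjusted p = 0.423 with an estimated correlation) and peripheral nerve (median 1.39, camera adjusted p = 0.000131, adjusted p = 0.423 with an estimated correlation) rose with 5 members each past adjusted over the list alone, and both were highest in chlordecone 2. The adipose median was 0.85 without chlordecone 2.

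Leukocyte markers had a median of 0.87 over 18 members (camera adjusted p = 0.00761, adjusted p = 0.480 with an estimated correlation) and interferon response genes a median of 0.68 over 21 members (camera adjusted p = 0.0446, adjusted p = 0.617 with an estimated correlation), with 0 members past adjusted over the list alone in both. The leukocyte call ended without control 1 (adjusted p = 0.0530) and without chlordecone 3 (median 0.41, adjusted p = 0.0849). That of interferon ended without control 2 (adjusted p = 0.107), without chlordecone 1 (adjusted p = 0.0620) and without chlordecone 3 (median 0.28, adjusted p = 0.375). Seminal vesicle markers did not pass (camera adjusted p = 0.867), their median of -0.07 and mean of 0.68 having opposite signs. Its median log2 ratio to the controls was -0.89, 1.19 and -4.53 in chlordecone 1, 2 and 3. The 4 members past adjusted over the list alone were Svs2, Svs5 and Pate4, higher in all 3 chlordecone libraries, and 9530002B09Rik, lower in all 3. Without chlordecone 1 and 3 together, a check added after the data were seen, edgeR called 1226 genes, 330 higher and 896 lower, but only chlordecone 2 is left in its group and the spread then comes from the 2 controls alone, so these calls say nothing of differences between chlordecone libraries.

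**Figure D2:**
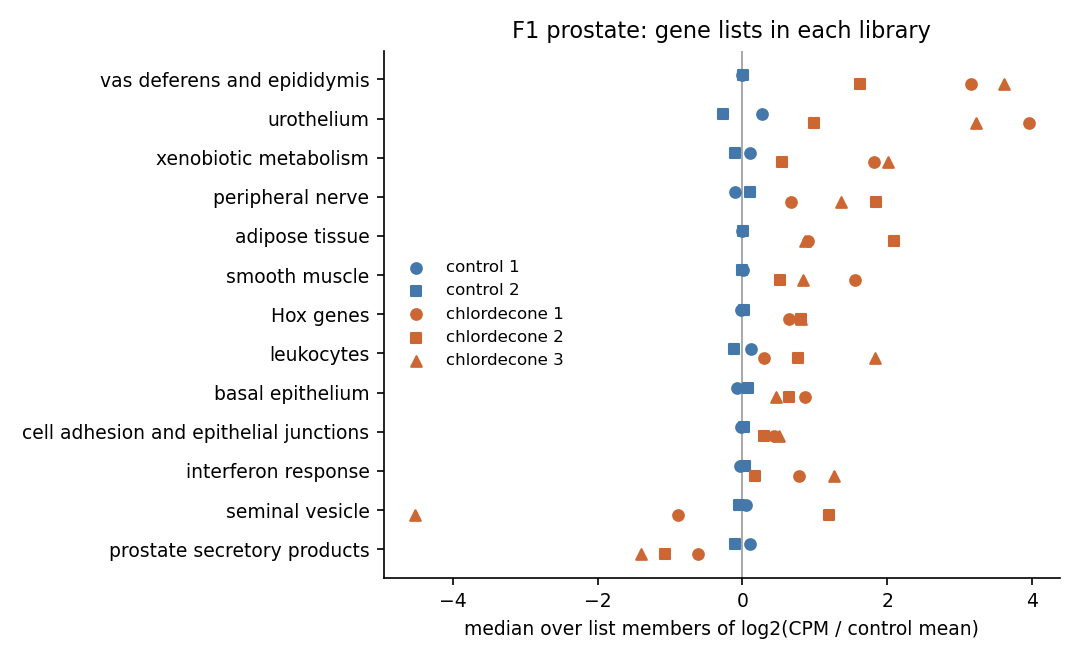
Median over list members of the log2 ratio of CPM to the control mean, for each F1 library (controls in blue, chlordecone in orange, 1 symbol per replicate number), for the 12 lists past the threshold with camera and the seminal vesicle list. Urothelium, vas deferens and xenobiotic markers are highest in chlordecone 1 and 3, and the seminal vesicle list stands at -4.53 in chlordecone 3 and 1.19 in chlordecone 2.

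The hormone pathway lists did not pass camera in F1. Androgen-responsive genes had a median of 0.14 over 20 members (camera adjusted p = 0.715), oestrogen-responsive genes 0.47 over 14 (camera adjusted p = 0.145) and steroid receptors and steroid metabolism -0.43 over 17 (camera adjusted p = 0.176), at -0.70, -0.56 and -0.53 in chlordecone 1, 2 and 3. The mixed fry test passed for androgen-responsive genes (adjusted p = 0.00893) and for steroid receptors and steroid metabolism (adjusted p = 0.0257) and not for oestrogen-responsive genes (adjusted p = 0.110). Single members stood out adjusted over the list alone: 7 oestrogen-responsive genes, among them Greb1 (93.7 ± 11.5 CPM in controls and 40.8 ± 12.3 CPM in chlordecone libraries) and Wnt4 (4.31 ± 0.654 and 12.4 ± 1.57 CPM), and 2 androgen-responsive genes, Fkbp5 (12.4 ± 3.11 and 43.8 ± 16.3 CPM) and Homer2 (1.31 ± 0.142 and 5.73 ± 0.637 CPM). Of steroid receptors and steroid metabolism, 0 members passed adjusted over the list alone. The other lists that did not pass had adjusted p from 0.0555 for fibroblast and extracellular matrix to 0.965 for p53 targets (median -0.04, mean 0.07).

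The F3 comparison asks whether prostate transcripts still differed in great-grandsons of the dosed females. Ren1, which encodes renin, fell from 5385 ± 2102 CPM (SD, n = 3) to 13.2 ± 4.11 CPM (n = 3), a level 406-fold lower. Ubash3b, a phosphatase that restrains receptor signalling, rose from 0.346 ± 0.0310 to 7.39 ± 0.877 CPM, 21.2-fold. Ms4a5 rose from 0 counts in the 3 controls to 5.59 ± 0.407 CPM, at least 169-fold higher against a floor of 0.0330 CPM. Upk1a, a uroplakin of the urothelial surface, rose 5.52-fold, from 3.00 ± 0.676 to 16.6 ± 3.12 CPM. Fmod, the collagen-binding proteoglycan fibromodulin, fell from 31.5 ± 0.777 to 13.4 ± 2.05 CPM, Fut4, a fucosyltransferase, from 5.90 ± 0.546 to 1.47 ± 0.252 CPM, and Lsm6, part of the spliceosome and of messenger RNA decay complexes, from 39.9 ± 0.606 to 19.1 ± 2.26 CPM.

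**Figure D3:**
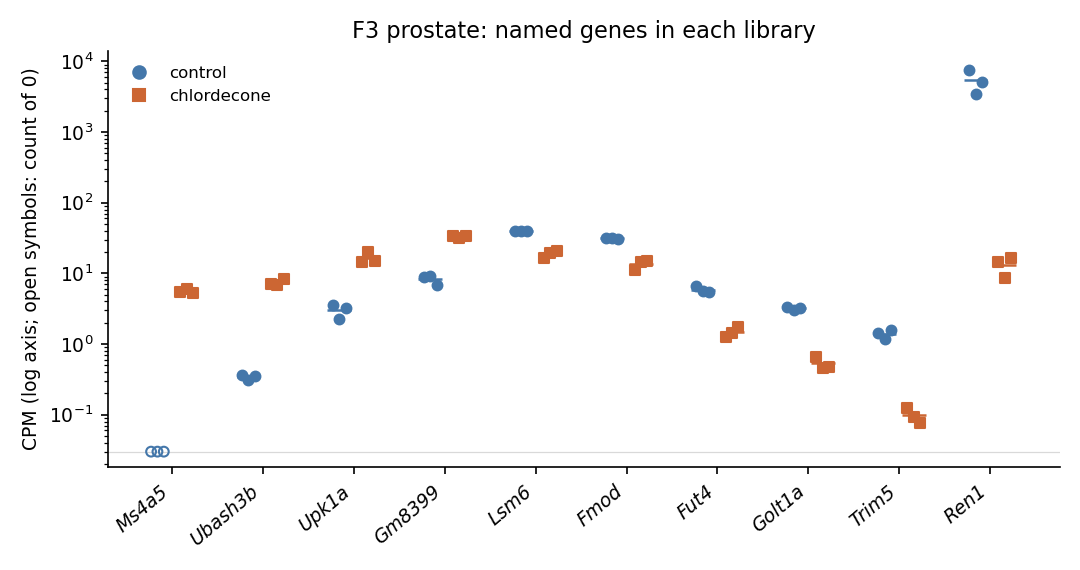
CPM (log axis) of the named genes in each F3 library, control (3 libraries, circles) and chlordecone (3 libraries, squares), with horizontal lines at the group means and open symbols for a count of 0. Ren1 stands at 3398 CPM or more in every control and at 16.6 CPM or less in every chlordecone library.

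Golt1a, a vesicle transport gene next to Ren1, fell from 3.22 ± 0.156 to 0.531 ± 0.108 CPM. The other genes past the threshold fell outside the naming rule and were picked after their values were seen: Gm8399, a processed pseudogene whose reads are uncertain, rose from 8.27 ± 1.28 to 33.1 ± 1.15 CPM, and Trim5, an antiviral restriction factor with a mean under 1 CPM, fell from 1.41 ± 0.208 to 0.0980 ± 0.0255 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 10 of 16766 genes passed, 4 higher and 6 lower. The log2 fold changes were -8.67 (SE 0.46, adjusted p = 0.000381) for Ren1, 4.41 (SE 0.22, adjusted p = 0.000381) for Ubash3b and 2.46 (SE 0.23, adjusted p = 0.0102) for Upk1a, and the adjusted p of Ms4a5 was 0.000789. They were -2.60 (SE 0.25, adjusted p = 0.0119) for Golt1a, -2.00 (SE 0.21, adjusted p = 0.0231) for Fut4, -1.23 (SE 0.14, adjusted p = 0.0399) for Fmod and -1.07 (SE 0.13, adjusted p = 0.0460) for Lsm6. Gm8399 had an adjusted p of 0.00272 and Trim5 of 0.0102 in edgeR. DESeq2 called 230 genes, 106 higher and 124 lower, with all 10 among them, and 1780 genes had an unadjusted p under 0.05, where chance gives 838. Groups did not overlap in 16.6% of the genes, against 10% by chance.

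Ren1 lies on chromosome 1 from 133350510 to 133360325, with Golt1a at 133309800 to 133323026 and Fmod at 134037254 to 134048277, in GRCm38. Golt1a overlaps Gm28040 and Kiss1 on its own strand, so its reads are uncertain. In the 3 Mb of chromosome 1 around them, 49 genes were tested, of which these 3 passed and 6 had an unadjusted p under 0.05, Gm28040, Etnk2 and Optc being the others. Ubash3b lies on chromosome 9 (41011098 to 41161697, over numbered gene models on both strands), Ms4a5 on chromosome 19 (11273238 to 11283873, over 4930526L06Rik on the other strand), Upk1a on chromosome 7 (30603092 to 30612847), Fut4 on chromosome 9 (14748320 to 14752393) and Lsm6 on chromosome 8 (78804865 to 78821140). The reads of Ubash3b and Ms4a5, and those of Trim5, which overlaps a numbered gene model, are uncertain. Leaving out each library in turn kept Ren1, Ubash3b, Ms4a5 and Gm8399 past the threshold. The count was 41 without control 1, which kept all 10, and 17 without control 2. Without control 2, Fmod (adjusted p = 0.0780) and Lsm6 (0.0763) were lost; without control 3, Upk1a (0.0605), Golt1a (0.0590), Fut4 (0.0710), Fmod (0.105), Lsm6 (0.126) and Trim5 (0.0528). Without chlordecone 1, Fut4 (0.139), Fmod (0.139) and Lsm6 (0.224) were lost; without chlordecone 2, these (0.168, 0.199 and 0.237) with Golt1a (0.103) and Trim5 (0.0755). Without chlordecone 3, Golt1a (0.0737), Fut4 (0.0612), Fmod (0.114) and Lsm6 (0.119) were lost.

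**Figure D4:**
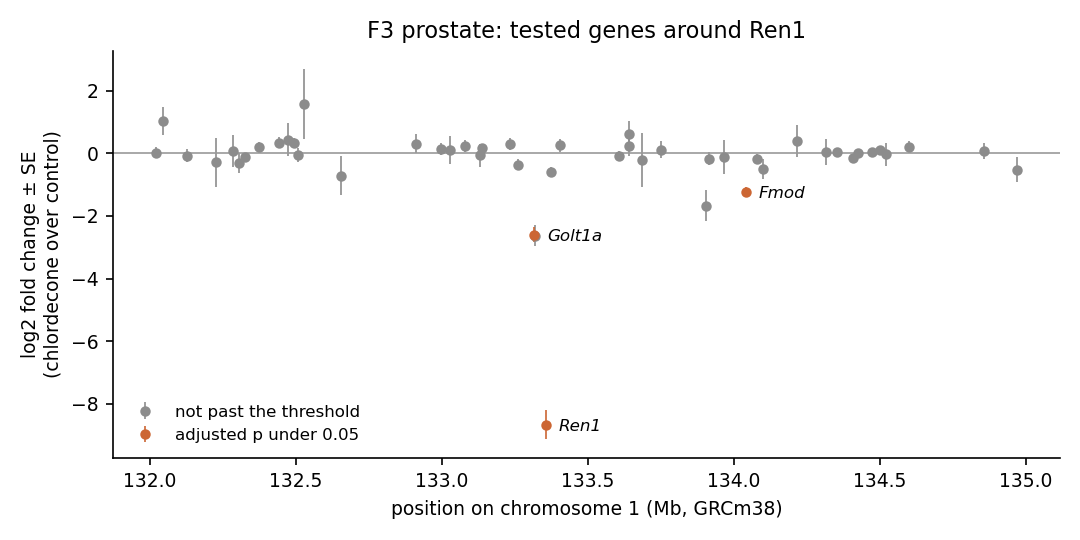
Log2 fold change of chlordecone over control (points, bars ± SE) in F3 for the 49 genes tested in 3 Mb of chromosome 1 around Ren1 (GRCm38). Ren1, Golt1a and Fmod, in orange, passed the threshold and all lie below 0.

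Of the 31 lists tested in F3, 10 passed camera, 4 higher and 6 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.225, 2 lists at an unadjusted p under 0.05) or with directional fry (lowest adjusted p = 0.0682, 6 lists at an unadjusted p under 0.05). The mixed fry test, which ignores direction, passed 6. Interferon response genes fell, all 22 members being lower, with a median log2 fold change of -1.07 (camera adjusted p = 1.27e-11, adjusted p = 0.417 with an estimated correlation). With edgeR, 0 members passed over all genes and 10 adjusted over the list alone, among them Usp18 (13.3 ± 9.24 CPM in controls and 4.22 ± 0.554 CPM in chlordecone libraries), Isg15 (6.06 ± 2.38 and 2.03 ± 0.733 CPM) and the immunoproteasome subunit Psmb8 (14.2 ± 3.45 and 6.95 ± 0.969 CPM). Isg15 was at 8.79, 4.38 and 5.01 CPM in control 1, 2 and 3. Control 1 was the highest library of the list, and without it the median of the list was -0.58. Seminal vesicle markers fell, all 9 members being lower, with a median of -1.79, or -1.13 without control 2 (camera adjusted p = 7.07e-06, adjusted p = 0.486 with an estimated correlation). Of these, 4 passed adjusted over the list alone, such as Svs4 (25.4 ± 18.6 and 8.05 ± 1.73 CPM), and the median log2 ratio of the list to the control mean was 0.72, 0.98 and -1.58 in control 1, 2 and 3 and -1.28, -0.99 and -1.67 in chlordecone 1, 2 and 3.

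Nuclear-encoded oxidative phosphorylation genes fell by a small amount, 25 of 28 members being lower with a median of -0.26 (camera adjusted p = 1.07e-07, adjusted p = 0.463 with an estimated correlation), and Cox5b (82.7 ± 4.59 and 58.1 ± 2.34 CPM) was the 1 member past adjusted over the list alone. Ribosomal protein genes fell, 29 of 30 being lower with a median of -0.20 and 0 past adjusted over the list alone (camera adjusted p = 0.000515, adjusted p = 0.693 with an estimated correlation). That call ended without control 2 (median -0.07, adjusted p = 0.168) and without chlordecone 1 (median -0.11, adjusted p = 0.0582), and the median was -0.34 without chlordecone 3. Leukocyte markers fell with a median of -0.27 over 22 members, 0 past adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.693 with an estimated correlation). The leukocyte median was -0.15 without chlordecone 1 and -0.79 without chlordecone 3, and the call ended without control 2 (median -0.10, adjusted p = 0.0647). Immediate early and heat shock genes fell with a median of -0.14 over 22 members, 0 past adjusted over the list alone (camera adjusted p = 0.0328, adjusted p = 0.417 with an estimated correlation). That call ended without control 2 (adjusted p = 0.0956), without control 3 (median -0.23, adjusted p = 0.0551) and without chlordecone 3 (adjusted p = 0.0677). The number of lists past the threshold was 17 without control 1.

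Urothelium rose in F3 with a median of 0.63 over 5 members, and Upk1a, past over all genes, and Upk1b (107 ± 7.26 and 165 ± 15.2 CPM) passed adjusted over the list alone (camera adjusted p = 7.07e-06, adjusted p = 0.225 with an estimated correlation). Its median was 0.40 without control 1 and 0.39 without chlordecone 2. Its median log2 ratio to the control mean was -0.02, 0.48 and 0.74 in chlordecone 1, 2 and 3, so chlordecone 1 lay among the controls (-0.25, -0.04 and 0.14). Basal epithelium rose, 9 of 11 members being higher with a median of 0.31 (camera adjusted p = 0.00182, adjusted p = 0.507 with an estimated correlation), and Krt15 (68.4 ± 7.09 and 106 ± 21.8 CPM) and Col17a1, a collagen of the basement membrane anchor, passed adjusted over the list alone. The Hox family rose, 14 of 24 members being higher and 10 lower, with a median of 0.18, or 0.35 without control 1 and 0.34 without control 2 (camera adjusted p = 0.00238, adjusted p = 0.417 with an estimated correlation). Chlordecone 2 (0.21) lay between control 3 (0.20) and control 2 (0.31) in the median log2 ratio of the Hox list. The 5 members past adjusted over the list alone were all of the A cluster, among them Hoxa7 (1.42 ± 0.338 and 4.46 ± 0.454 CPM), Hoxa9 (13.1 ± 2.16 and 22.2 ± 2.59 CPM) and Hoxa10 (19.2 ± 4.39 and 31.8 ± 3.92 CPM). Cell adhesion genes rose with a median of 0.15 over 25 members, Cldn1 (12.4 ± 0.547 and 18.5 ± 1.26 CPM) being the 1 past adjusted over the list alone (camera adjusted p = 0.0390, adjusted p = 0.507 with an estimated correlation). That call ended without control 1 (adjusted p = 0.124), without control 2 (median 0.07, adjusted p = 0.168), without chlordecone 1 (adjusted p = 0.0582) and without chlordecone 2 (adjusted p = 0.0617), and the median was 0.24 without control 3.

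**Figure D5:**
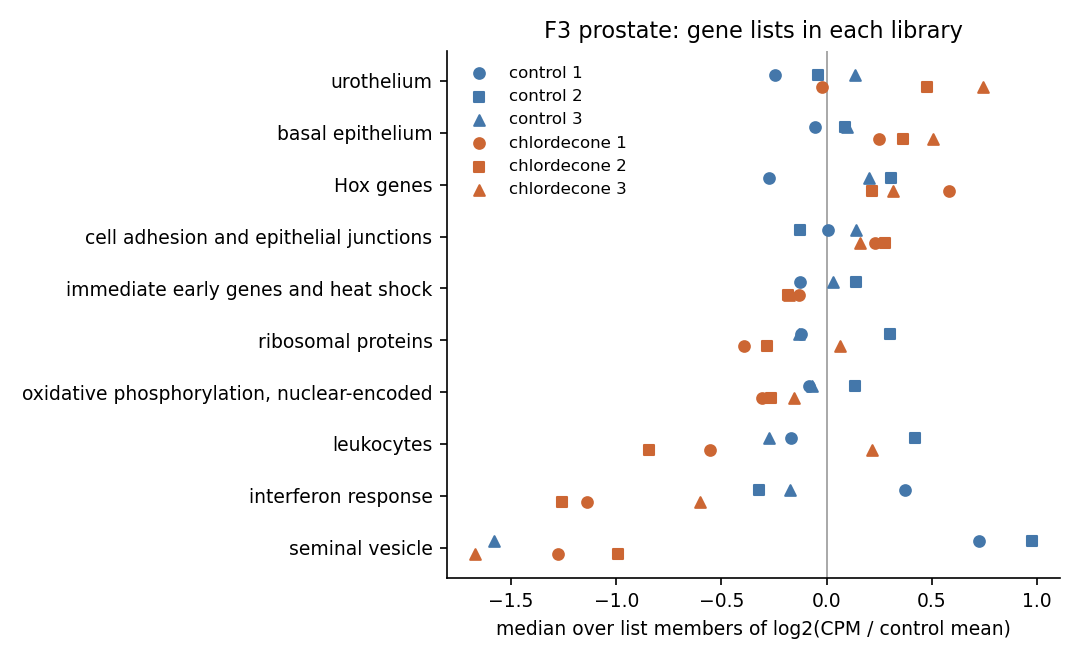
Median over list members of the log2 ratio of CPM to the control mean, for each F3 library (controls in blue, chlordecone in orange, 1 symbol per replicate number), for the 10 lists past the threshold with camera. The interferon list stands at -1.14, -1.26 and -0.60 in the chlordecone libraries, and for the seminal vesicle list control 3 lies among the chlordecone libraries.

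Prostate products did not pass in F3 (median 0.26 over 8 members, camera adjusted p = 0.362): Tgm4 was at 69626 ± 4915 and 73214 ± 7045 CPM and Pbsn at 26741 ± 6176 and 18543 ± 1797 CPM. Androgen-responsive genes had a median of 0.15 over 20 members (camera adjusted p = 0.0896), oestrogen-responsive genes 0.04 over 11 (camera adjusted p = 0.510), and steroid receptors and steroid metabolism 0.01 over 15 (camera adjusted p = 0.673, with a mean of -0.06), each with 0 members past over all genes and 0 adjusted over the list alone with edgeR. The mixed fry test passed for androgen-responsive genes (adjusted p = 0.0407). It did not pass for oestrogen-responsive genes (mixed fry adjusted p = 0.437) or for steroid receptors and steroid metabolism (0.103). Chromatin and DNA methylation regulators had a median of 0.17 over 24 members (camera adjusted p = 0.0555), against -0.13 over 25 in F1 (camera adjusted p = 0.878). The other lists that did not pass in F3 had adjusted p up to 0.841, that of endothelium.

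The comparison of the generations asks whether the F1 differences were carried to F3. Ren1 and Gm8399 were not tested in F1, and Cyp21a1 was not tested in F3, so these genes could not be compared. Among 14079 genes tested in both, 4 were called in F1 and 8 in F3 by edgeR, with 0 shared in the same and 0 in the opposite direction. Independent lists of these sizes would share 0.000213 higher and 0.00107 lower genes, so this count of 0 says nothing of whether differences were carried. Of the lists, 4 passed camera as higher in both generations, the Hox family, basal epithelium, urothelium and cell adhesion, none of them with an estimated correlation. The interaction of these lists did not pass (camera adjusted p = 0.643, 0.195, 0.1297 and 0.315 in that order), which does not show that their effects were alike. Nor need the same genes lie behind both calls. Hox members past adjusted over the list alone were of the B and D clusters in F1 and of the A cluster in F3. Of the urothelial members past in F3, Upk1a had log2 fold changes of 3.01 in F1 and 2.46 in F3, and Upk1b -0.23 and 0.63. At an unadjusted p under 0.05, 63 genes were higher in both (68.2 expected from independent lists, Fisher's exact test, two-sided, p = 0.557), 22 lower in both (27.5 expected, p = 0.317), 95 higher in F1 and lower in F3 (71.8 expected, p = 0.00410) and 43 lower in F1 and higher in F3 (26.2 expected, p = 0.00138). With DESeq2, 12 of 17039 genes were higher in both (2.78 expected, Fisher's exact p = 2.03e-05), 3 lower in both (0.993 expected, p = 0.0775), 12 higher in F1 and lower in F3 (3.42 expected, p = 0.000159) and 3 lower in F1 and higher in F3 (0.806 expected, p = 0.0471), so the excess lay in opposite directions as well. Across genes, which are not independent replicates, the log2 fold changes of F1 and F3 had a Pearson r of -0.06 and a Spearman rho of -0.09. Without F3 control 2 the Pearson r was 0.02 and the Spearman rho -0.01.

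With edgeR's interaction test, the difference between chlordecone and control libraries changed between F1 and F3 for 122 of 16980 genes. Of these, 43 had F3 above F1 and 79 below. The count was 1150 with DESeq2, and 2878 genes had an unadjusted p under 0.05 with edgeR. The 6 with the smallest p were Ubash3b, Fmod, Fam199x, C1rl, Trim5 and Golt1a. Ubash3b was at 9.16 ± 0.233 and 9.06 ± 2.19 CPM in F1 control and chlordecone libraries and at 0.368 ± 0.0387 and 8.12 ± 0.841 CPM in F3, so the F3 controls were the low group (levels across tables that were made separately). Fam199x stood at 236 ± 4.86 CPM in F1 controls and at 5.86 ± 2.20 CPM in F1 chlordecone libraries, 13.9 ± 4.26 CPM in F3 controls and a mean of 19.1 CPM in F3 chlordecone libraries. Fmod was at 0.767 ± 0.124 and 5.94 ± 1.67 CPM in F1 and at 33.5 ± 1.63 and 14.7 ± 2.13 CPM in F3. Their interaction log2 values were 4.47 (SE 0.41, adjusted p = 0.000777 in edgeR) for Ubash3b, 5.80 (SE 0.58, adjusted p = 0.00102) for Fam199x and -4.14 (SE 0.39, adjusted p = 0.000777) for Fmod. The interaction test used 1 estimate of spread per gene for both generations. The coefficient of variation between libraries, common to all genes, was 0.523 in F1 and 0.258 in F3. The F1 spread can therefore be understated in these calls: the SE of Fmod in the F1 fit alone was 0.60. The interaction count was 54 without F1 control 1, 41 without F1 control 2, 2320 without F1 chlordecone 2, 55 without F3 control 2, 70 without F3 control 3, 27 without F3 chlordecone 1, 27 without F3 chlordecone 2 and 36 without F3 chlordecone 3.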

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

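The tests of tissue carried into F1 libraries, of the 50 genes chosen without chlordecone 2, of the interferon list, of the position of F3 genes and of the splits were chosen after the results were seen, while the tests of an untreated library over all called genes, of overlapping genes and of gene families were set beforehand. For the genes of this paragraph the difference between chlordecone and control libraries changed between F1 and F3 with edgeR's interaction test, Benjamini-Hochberg adjusted. The test compares groups and does not show that the exposure was the cause. The interaction log2 value, F3 minus F1, was 4.47 for Ubash3b (adjusted p = 0.000777), 5.80 for Fam199x (adjusted p = 0.00102), 4.66 for C1rl (adjusted p = 0.00103) and 3.52 for Scn3a (adjusted p = 0.0196). It was -4.14 for Fmod (adjusted p = 0.000777), -3.83 for Golt1a (adjusted p = 0.00135), -5.82 for Pfkfb3 (adjusted p = 0.00250), -6.94 for Bex2 (adjusted p = 0.00458), -3.45 for Kcna2 (adjusted p = 0.00485) and -3.68 for Fut4 (adjusted p = 0.0471). For Trim5 it was -14.2 (adjusted p = 0.00103) and for Ms4a5 9.53 (adjusted p = 0.0474), and both values depend on the prior count, since a group of each was at 0 in every library. The lists were tested with camera on the interaction, and none of these calls held with an estimated correlation. Their median interaction was 1.12 for prostate products (camera adjusted p = 0.000849, adjusted p = 0.371 with an estimated correlation) and -1.43 for smooth muscle (camera adjusted p = 1.23e-06, adjusted p = 0.697 with an estimated correlation). It was -1.26 for leukocytes (camera adjusted p = 0.00132, adjusted p = 0.697 with an estimated correlation), -1.78 for xenobiotic metabolism (camera adjusted p = 7.04e-05, adjusted p = 0.371 with an estimated correlation) and -1.73 for interferon response (camera adjusted p = 2.19e-05, adjusted p = 0.371 with an estimated correlation). Interaction counts, library dependence and the limit from a shared estimate of spread are those given with the comparison of the generations.

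F1 chlordecone 1 and 3 stood apart from chlordecone 2. Tissue of the vas deferens or epididymis carried into both libraries stays open, since 3 of 6 of its markers, Akr1b7, Crisp1 and Spink8, were over 4-fold above the controls in both. Gpx5, Rnase10 and Lcn5 had control means of only 0.105, 0.422 and 0.314 CPM, too low to weigh against it. Seminal vesicle tissue carried into both is argued against as the whole cause, since its markers parted: 4 of 11 were over 2-fold below the controls in both (Sva at a log2 ratio of -9.47 in chlordecone 3, 9530002B09Rik as low in chlordecone 2), while Svs2, Svs5 and Pate4 were over 2-fold above in both. Whether chlordecone 2 is an untreated library stays open. At all 2601 genes called without it, it lay on the side of chlordecone 1 and 3 at 65.9%, with a slope of 0.33. This share fell between the bounds set beforehand for either answer. Of the 50 genes with the smallest p without it, it lay on that side at 49 and over 2-fold from the control mean at 36. These 50 cannot decide it, since they were chosen after the results with the same 2 controls. That choice favours controls close together, and neither lay more than a log2 of 0.62 away. An effect of chlordecone that varied between males stays open as well and was not tested.

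The interferon response list was lower in F3 chlordecone libraries. Control 1 alone is argued against as the whole cause, since without it the median was -0.58, with an upper quartile of -0.41 and 21 of 22 members below 0. An even loss of leukocytes is argued against as the whole cause, since the leukocyte list had a median of -0.27. Its lower quartile was -0.54, above the interferon median of -1.07. Loss of 1 type of leukocyte stays open and was not tested. Of the chlordecone libraries, both lists were lowest in chlordecone 2 (leukocytes -0.85, interferon -1.26) and highest in chlordecone 3 (0.22 and -0.60). Of the controls, the highest was control 2 for leukocytes and control 1 for interferon. Variation between samples that does not follow the groups stays open. With control 1, control 3 and chlordecone 3 set against the other libraries, the median of the list was -0.95. An effect of the ancestral exposure and a difference in the animals' infections or housing between groups stay open as well and were not tested.

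The F3 genes with the smallest p lay near each other: 18 of the top 50 had another within 1 Mb, against a median of 4 in random draws matched for expression (permutation p = 0.0001, the smallest that 10000 draws allow), while in F1 the number was 6 (permutation p = 0.299). Reads shared between overlapping genes are argued against as the whole cause: 16 were left when overlapping genes were not counted as each other's neighbour (permutation p = 0.0002; Golt1a and Gm28040, which overlap, both stay in), and 15 when 1 gene was kept of each overlapping set (permutation p = 0.0003, chosen after the result), and co-regulated gene families are argued against as the whole cause, with 9 left (permutation p = 0.0122) when related names and numbered gene models were not counted either. With those rules the permutation p was 0.0899 for a window of 5 Mb, 0.0185 for the top 100 and 0.0018 for the top 200. A haplotype that differs between the F3 groups, which descend from different females, would place changed genes in such neighbourhoods, as with Golt1a, Ren1 and Fmod, and it cannot be told from an inherited effect of the exposure because both follow the group. Of those 16 genes, 13 were also tested in F1, 2 with the same sign there and 11 with the opposite, beside 46.3% with the same sign among all genes tested in both.

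Splits of the same libraries into groups of the same sizes number 10 in each generation, too few for a share under 0.05. In F1, 2 of the 10 splits gave as many genes with edgeR (real value 5, highest other 1587), 2 as many with DESeq2 (real value 700, highest other 3036) and 2 as many lists (real value 12, highest other 14). The split with 1587 genes set chlordecone 1 and 3 against the other libraries, which points to a structure of the samples, whose nature stays open as above. In F3, 1 of the 10 splits gave as many genes with edgeR (real value 10, highest other 4), 2 as many with DESeq2 (real value 230, highest other 374) and 5 as many lists (real value 10, highest other 15).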

How the results depend on the processing

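The tests with newer quasi-likelihood moments, with voom quality weights and without F1 chlordecone 1 and 3 together were chosen after the data were seen. Among values for single genes, 282 kept their direction and side of the threshold, 39 became stronger and 46 weaker, and among values for single lists 173 were kept and 69 became weaker. Of the counts 47 stayed within 1.5-fold and 34 did not. The F1 gene count of 5 was 21 with no filter, 700 with DESeq2, 930 in 1 fit of all libraries, 322 with the replicate number as a block, 20 with newer moments, 1617 with voom weights (chlordecone 2 at a weight of 0.269), 1226 without chlordecone 1 and 3 together and from 0 to 2604 with each library left out. The 0 held with edgeR without control 1 (1066 genes at an unadjusted p under 0.05), without control 2 (1059) and without chlordecone 3 (1240), and 2604 held without chlordecone 2. The F3 gene count of 10 was 38 with no filter, 230 with DESeq2, 2 in 1 fit of all libraries and from 7 to 41 with each library left out, 41 without control 1 and 17 without control 2. The list counts, 12 in F1 and 10 in F3, were 0 in both generations with an estimated correlation (1 and 2 lists at an unadjusted p under 0.05) and 0 with fry (4 and 6 lists), and from 8 to 17 in F3 with each library left out, 17 without control 1. The interaction count of 122 was 1150 with DESeq2, 49 with the block and from 27 to 2320 with each library left out, 2320 without F1 chlordecone 2. The overlap of 0 genes in the same direction with edgeR was 15 with DESeq2, 85 at an unadjusted p under 0.05 and from 0 to 1 with each library left out, 1 without F1 chlordecone 2. The Pearson correlation of the log2 fold changes reversed from -0.0596 to 0.0195 without F3 control 2, in a range of -0.0761 to 0.0195. The Spearman rho stayed below 0 there, at -0.0127 against -0.0896. The cause of these shifts was not tested, except that leaving out a library leaves fewer samples. A fit with 1 library in a group assumes that it varies like the other group, whose spread alone is measured, as without F1 chlordecone 1 and 3 together. The replicate number was not used as a block in the comparisons reported, since deviations of libraries with the same number had r of 0.131, 0.0018 and 0.0019 in F3 and 0.0483 and 0.0583 in F1. Both F1 controls and F3 control 1 correlated best with their own number, and F3 control 2 (0.206 with chlordecone 3) and F3 control 3 (0.0726 with chlordecone 1) did not. Alternatives for normalized values were not run, since the tables hold counts. In simulated F1 data edgeR recovered 1% of genes with a log2 change of 1, against 58% in F3.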

Other observations

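The comparison of authors' calls and the levels set side by side here were chosen after the results were seen, and no tests were added to them. Single genes of lists that did not pass stood out in both generations. In F1, Scd1, a fatty acid desaturase, was at 23.4 ± 3.89 CPM in controls and 68.0 ± 13.5 CPM in chlordecone libraries, and Elovl6, a fatty acid elongase, at 4.68 ± 0.194 and 23.3 ± 16.1 CPM, the 2 members of cholesterol and fatty acid synthesis past adjusted over the list alone with edgeR (0 over all genes; list median 0.37, camera adjusted p = 0.0726). In F3, Dbp, an output gene of the circadian clock, was at 52.9 ± 13.6 and 22.2 ± 8.27 CPM, the 1 member of the clock list past adjusted over the list alone (0 over all genes; list median 0.08, camera adjusted p = 0.558). Sprr1a, a cornified envelope protein, was at a mean of 0.412 CPM in controls and 3.05 CPM in chlordecone libraries in F3, 1 of 2 members of the squamous list past adjusted over the list alone (0 over all genes; list median -0.05, mean 1.02, camera adjusted p = 0.0555).

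Levels of some secretory transcripts differed across the 2 tables, which were made separately. Whether the samples or the processing differed was not tested. Svs4 was at 79425 CPM in F1 controls and at 25.4 CPM in F3 controls, and Tgm4 at 8259 and 69626 CPM. Svs5 was at 19697 and 10.5 CPM. If the samples held unlike shares of seminal vesicle tissue, the interaction between generations compared unlike mixtures of tissue.

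In the authors' deposited table, 644 genes had an adjusted p under 0.05 in F1, 510 higher and 134 lower, and all 5 genes called here by edgeR were among them. In the authors' deposited table for F3 the number was 168, 79 higher and 89 lower, with all 10 genes called here among them. In the authors' deposited tables, past in both generations were 21 genes, 10 in the same direction and 11 in opposite directions.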
